A study of Mus musculus with 6 samples.

How the data were processed

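Total RNA was profiled on 6 arrays of mouse mammary material. The wild-type group held 3 samples of luminal epithelial cells, sorted for yellow fluorescent protein 10 to 14 days after an adenovirus carrying Cre recombinase under a keratin 8 promoter had been injected into the ducts of reporter females. The tumor group held 3 mammary tumors that developed several months after the same virus had been given to females with L/L alleles of Trp53 and Brca1. Per the labels, wild-type arrays came from different mice and the tumors carry different numbers, but the labels do not say whether each tumor came from a mouse of its own. If they shared an animal, p-values measure in part the spread between pieces of 1 animal. Per the labels, the RNA was amplified with a NuGEN kit and labelled with biotin.

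The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the tools were RMA (background correction, quantile normalization and summary of probes into probe sets) and oligo; their versions are not given in the sources used here. RMA forces the arrays towards a common distribution before summary, and it compresses differences of genes close to background. The deposited columns still differed slightly, with probe set medians of 3.25 to 3.59. No scanner files were used, so neither detection calls nor scan dates entered, and no batch could be tested. Array data give no read depth, and the number of arrays limits the precision.

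The table held 41345 probe sets. Gene names came from the platform annotation supplied with the table: 23521 probe sets named 1 gene, 1814 named several and 16010 named none. Of the 23521, 23328 were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6, and 193 kept the platform's symbol. No column of the table was left unmapped to a sample. The probe set with the highest mean over the 6 arrays stood for each of 22180 genes, of which 1082 had more than 1 probe set. The files give no probe coordinates, so genomic positions are not reported. Trp53 and Krt5 had no probe set naming them alone in the table used and were not analysed here.

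Tumors were compared with wild-type cells with limma 3.58.1 (lmFit and eBayes, R 4.3.3), without covariates and without a filter on dim genes, two-sided. Every adjusted p for a gene is from this limma fit with Benjamini-Hochberg adjustment over 22180 genes, with a threshold of 0.05. Differences are log2 values, tumor minus wild type, with the moderated standard error. Group levels are means ± SD over 3 arrays. For 29 gene lists, limma's camera was run with a preset correlation between genes of 0.01 and adjusted over the 29 lists. Camera with an estimated correlation and fry, limma's rotation test for a shift of the list on balance in one direction, were alternatives. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. The labels give no shared replicate numbers between groups. The named genes are the targeted genes, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, the 4 largest called changes of each list (or 2 values where none passed), and a fixed set of lineage genes.

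As a mark for background, chosen after the data were seen, the 95th percentile of 1105 olfactory receptor genes was taken on each array. It lay between 3.70 and 3.86 on the wild-type arrays and between 3.24 and 3.45 on the tumor arrays. Values under this mark are not told from background here, and a fold against them is the difference of RMA values only. Of the named genes that rose, Brca1, Brca2, Bub1, Elf5 and Slc38a3 lay under it on all 3 wild-type arrays, and Nkd2, Zfp960, Mmp12, Pla2g7, Cenpf, Chaf1a, Ckap2 and Pdgfrb on 2. Of those that fell, Fgg, Fgb, Reg3g, Pgr and Msx2 lay under it on all 3 tumor arrays, and Cxcl15 and Il6 on 2.

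The limma step was tested on simulated data with the 22180 genes' own means and spreads and 200 changed genes. It recovered 30% of genes changed by 1 log2 unit, 80% of those changed by 2, 78% of those changed by 3 and 88% of those changed by 4. Of 142 calls, 2.82% were false. Camera called at least 1 list in 1 of 100 simulated data sets without a shift. In another set, with the ribosomal list shifted by 1, it called that list and, falsely, the unshifted interferon-stimulated list (adjusted p of 0.0049, and 0.0091 before the shift). These simulated genes were independent of each other, which real genes of a pathway are not.

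The alternatives were 2 filters on dim genes (a mean of at least 5, or of at least the median), the mean of a gene's probe sets, probe sets tested singly, quantile normalization again, centring on the housekeeping list, cyclic loess, a trended robust prior, array weights, the other set tests, and leaving out each array in turn. Alternatives added after the data were seen were the mean of the skeletal muscle list as a covariate, tumor 24 alone, and comparison of list medians with 10000 random lists matched on mean expression. Lists with fewer than 3 measured genes were not tested. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for gene naming and plots.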

Results

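The data were log2 expression values of 22180 genes on 6 arrays, 3 of sorted wild-type luminal mammary cells (replicates 1, 2 and 4) and 3 of mammary tumors from females with L/L alleles of Trp53 and Brca1 (tumors 23, 24 and 25), which the labels call null for both genes. Trp53 encodes a stress-responsive transcription factor and Brca1 a factor of homologous recombination. The design asks how tumors differ from the luminal cells the labels name as their origin. Sorting is described for the wild-type cells alone, so the comparison sets sorted cells against tumor tissue. Pearson's correlations across genes lay between 0.938 and 0.966 among wild-type arrays, between 0.933 and 0.955 among tumors, and between 0.867 and 0.917 across the groups. The median over genes of the SD between arrays was 0.281 in tumors and 0.268 in wild-type cells, a ratio of 1.05. Without wild-type replicate 2 this ratio was highest, and over all 6 leave-one-out sets it ranged from 0.76 to 1.52.

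Of the targeted genes, Brca1 measured 3.88 ± 0.19 on the arrays labelled tumor and 2.93 ± 0.11 in wild-type cells (SD, n = 3), a rise of 0.94 ± 0.18 (SE) with an adjusted p of 0.044 in limma. It did not pass in any of the 6 leave-one-out sets. The wild-type values lay under the background mark and the tumor values above it. The labels name neither the deleted exons nor the probes' positions, so this measurement checks nothing about the labels. Groups are named throughout as the labels give them.

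Against wild-type luminal cells, the tumors (n = 3 and 3) had lower levels of the estrogen receptor gene Esr1, which fell by 2.67 ± 0.22 log2 units (SE), and of the immediate early gene Fos, which fell by 2.41 ± 0.21. The complement gene C1qa of macrophages rose by 4.09 ± 0.37, the matrix gene Fn1 by 3.39 ± 0.56, the proliferation marker Mki67 by 2.58 ± 0.42 and the angiogenic factor Vegfa by 2.44 ± 0.32. The luminal keratins Krt8 and Krt18 were 2.05 ± 0.48 and 2.09 ± 0.71 lower without passing the test. Of the 22180 genes, 867 passed limma's test after Benjamini-Hochberg adjustment, 559 higher and 308 lower in tumors, and 818 of them differed at least 2-fold (542 higher, 276 lower). The groups did not overlap for any of the 867, nor for 36.4% of all genes, where chance gives 10%. Bright genes lay higher in tumors: the median difference was 0.32 over genes with a mean of at least 5, against -0.12 over all genes. Probe set SDs ran from 1.96 to 2.00 on wild-type arrays and from 2.10 to 2.16 on tumor arrays. Small rises of lists of bright genes are not told from this shift. The split depended on scaling: 64.5% of calls were higher in tumors here, 44.3% after quantile normalization again, 52.3% after cyclic loess and 28.2% after centring on housekeeping genes, which moved the median difference of all genes from -0.12 to -0.59. All 867 genes kept their direction under these 3 scalings. Of the named genes, Axl, Mmp2 and Fas lost their call under all 3, Cenpf under the first and second, Gapdh under the first and the last, Kit and Fbln2 under the first, and Brca1, Brca2, Bub1, Chaf1a and Pgam1 under the last, while Krt8 passed downward under all 3. The count moved when single arrays were left out: it was 72 without wild-type replicate 4, 138 without replicate 1, 170 without replicate 2, 142 without tumor 23, 375 without tumor 25 and 1200 without tumor 24. Leaving out an array also leaves fewer degrees of freedom, and this was not separated from the part of the array itself. Of the genes named here, Nkd2, Zfp960, C1qa, C1qb, Fgg, Ctsr, Cxcl15, Tspan1, R3hdml, Fosb, Fos, Klf6, Esr1, Fxyd2 and Dgat2 passed in all 6 leave-one-out sets, and every other one that passed lost its call in at least 1 of them. As alternatives chosen after seeing the data, the mean of skeletal muscle genes as a covariate left 31 genes, and tumor 24 alone against wild type gave 0 in limma, with 3588 at an unadjusted p under 0.05.

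Of the 29 gene lists, 13 passed camera with its preset correlation, 10 upward and 3 downward. With a correlation estimated from the data 0 passed (2 at an unadjusted p under 0.05), with fry 8, and against random lists matched on expression 14. Other splits of the 6 arrays gave up to 15 lists, and each list that passed is given with its members and its p with an estimated correlation.

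**Figure D1:**
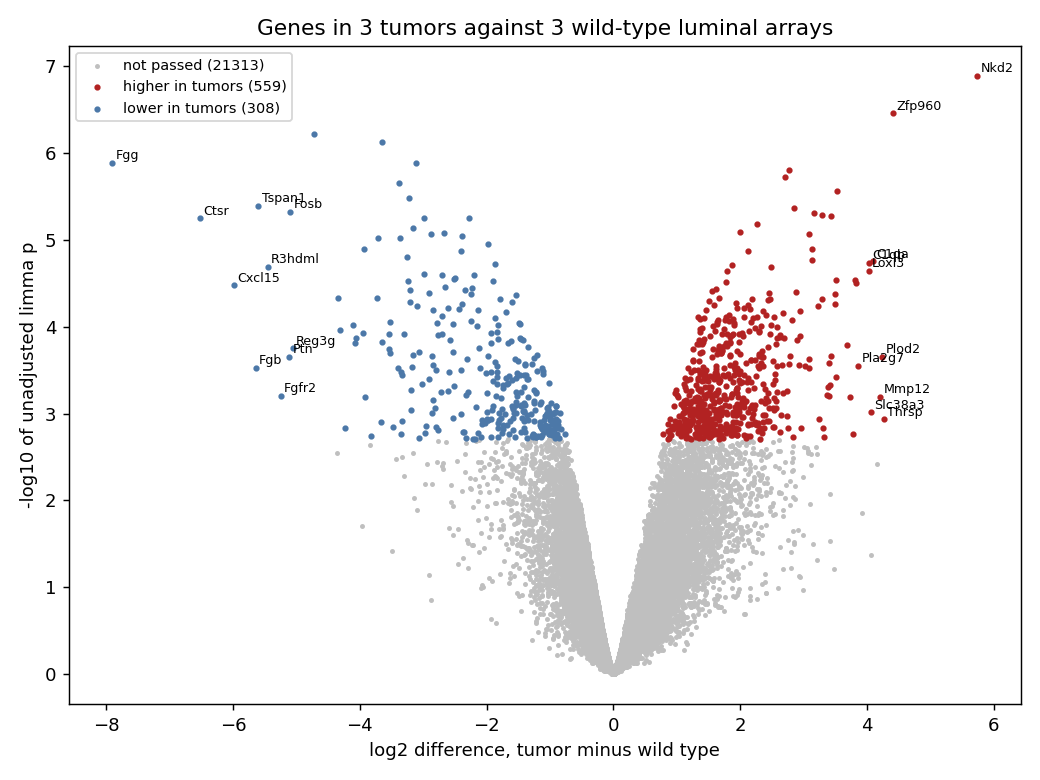
Each point is 1 gene, with the log2 difference (tumor minus wild type) on the x axis and -log10 of the unadjusted limma p on the y axis; red genes were called higher (559), blue genes lower (308), and names mark the 10 largest rises and falls. Nkd2 stands at the far right (5.74) and Fgg at the far left (-7.90).

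The largest rise in RMA values was that of Nkd2, a negative regulator of Wnt signalling, from 3.75 ± 0.37 to 9.49 ± 0.21 (SD, n = 3), with an adjusted p of 0.0029 in limma. Next came Zfp960 (4.41 log2 units), a zinc finger gene with close relatives whose probes can share signal, and Thrsp (4.26), a regulator of lipid synthesis. Plod2 (4.24), which hydroxylates collagen lysines, and Loxl3 (4.03), a lysyl oxidase relative, rose together with the macrophage elastase Mmp12 (4.21) and the complement genes C1qa (4.09) and C1qb (4.03). The amino acid transporter Slc38a3 rose by 4.06 and the phospholipase Pla2g7 by 3.86. Adjusted p over these 10 genes ran from 0.0029 to 0.041. Slc38a3 lay under the background mark on all 3 wild-type arrays, Nkd2, Zfp960, Mmp12 and Pla2g7 on 2, and Plod2 and Loxl3 on 1, so the sizes and the order of these rises are not settled.

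The largest fall was that of Fgg, the fibrinogen gamma chain, from 10.4 ± 0.99 to 2.47 ± 0.15 (SD, n = 3), a difference of -7.90 ± 0.48 (SE) with an adjusted p of 0.0048 in limma. Fgb, the fibrinogen beta chain, fell by 5.64 from 8.16 ± 1.74. The cathepsin gene Ctsr fell by 6.52, the chemokine Cxcl15 by 5.99, the tetraspanin Tspan1 by 5.61 and R3hdml by 5.45. Fgfr2, a fibroblast growth factor receptor, fell by 5.25, from 9.54 ± 0.15 to 4.29 ± 1.87. The growth factor Ptn fell by 5.12, the immediate early gene Fosb by 5.10 and the lectin Reg3g by 5.06. Tumor means of Fgg, Fgb, Cxcl15 and Reg3g lay under the background mark. Tspan1, R3hdml and Fgfr2 lay under it on 1 tumor array each, so the sizes and the order of these falls are not settled.

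Several genes of hormone-sensing luminal cells fell in the tumors. Esr1, the estrogen receptor, went from 6.75 ± 0.34 to 4.09 ± 0.06 (SD, n = 3), a 6.35-fold fall with an adjusted p of 0.0073 in limma. The progesterone receptor Pgr fell by 2.60 to values under the background mark in all 3 tumors, the pioneer factor Foxa1 by 3.07 and Fxyd2, a regulator of the sodium pump, by 3.64. Of 14 measured members of the list, 7 fell and none rose (10 fell adjusted over the list alone), and the median difference was -1.77. Camera with the preset correlation gave an adjusted p of 2.05e-07, and adjusted p = 0.25 with an estimated correlation. Epithelial keratins and adhesion genes were lower on average by less, with a list median of -1.19. Of 24 measured, 3 fell, the tight junction gene Ocln (by 3.06), Cd24a (by 1.80) and Spint2 (by 1.47), and 7 fell adjusted over the list alone. With the preset value camera gave an adjusted p of 9.46e-05, and adjusted p = 0.48 with an estimated correlation. The keratins Krt8 (-2.05 ± 0.48, SE) and Krt18 (-2.09 ± 0.71) did not pass, at adjusted p of 0.068 and 0.14 in limma; without tumor 24 they measured -1.54 and -1.26. Nor did the adhesion genes Epcam (-0.80) and Cdh1 (-0.82). The macrophage list, with a median of 1.66, was higher in the same tumors.

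Genes of luminal progenitors and milk-producing cells moved both ways. Kit, a receptor tyrosine kinase of luminal progenitors, rose from 6.61 ± 0.69 to 9.02 ± 0.63 (SD, n = 3), and Elf5, a transcription factor of the alveolar lineage, rose by 1.90 ± 0.28 (SE), with adjusted p of 0.042 and 0.026 in limma. Cxcl15 (by 5.99), the lactoferrin gene Ltf (by 3.54) and Aldh1a3 (by 2.72) fell. Of 19 measured members, 2 rose and 3 fell (3 and 5 adjusted over the list alone), and camera's adjusted p was 0.11 with a list median of -0.90; under the other scalings the list passed downward, at 0.019 after quantile normalization again, 0.019 after housekeeping centring and 0.0095 after cyclic loess. It also passed downward without wild-type replicate 4 (0.021) and without tumor 25 (0.0076). Among basal and myoepithelial genes, only the smooth muscle myosin Myh11 of 21 passed, and it fell by 1.40, also adjusted over the list alone. Camera's adjusted p was 0.62, upward, and the direction turned after quantile normalization again and cyclic loess. The basal list median against the wild-type mean was 0.79 in tumor 24, and -0.02 and -0.10 in tumors 23 and 25. The basal keratin Krt14 measured 9.79 ± 2.02 in tumors and 8.90 ± 0.40 in wild-type cells (SD, n = 3), with 11.64 in tumor 24 and 7.63 in tumor 25. Trp63, a basal transcription factor, was at 6.93 in tumor 24 and at 3.72 and 4.50 in tumors 23 and 25. The keratinocyte list mean was 4.73 in tumor 24 and 3.32 and 3.26 in tumors 23 and 25, against 3.91 to 4.12 in wild-type arrays.

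**Figure D2:**
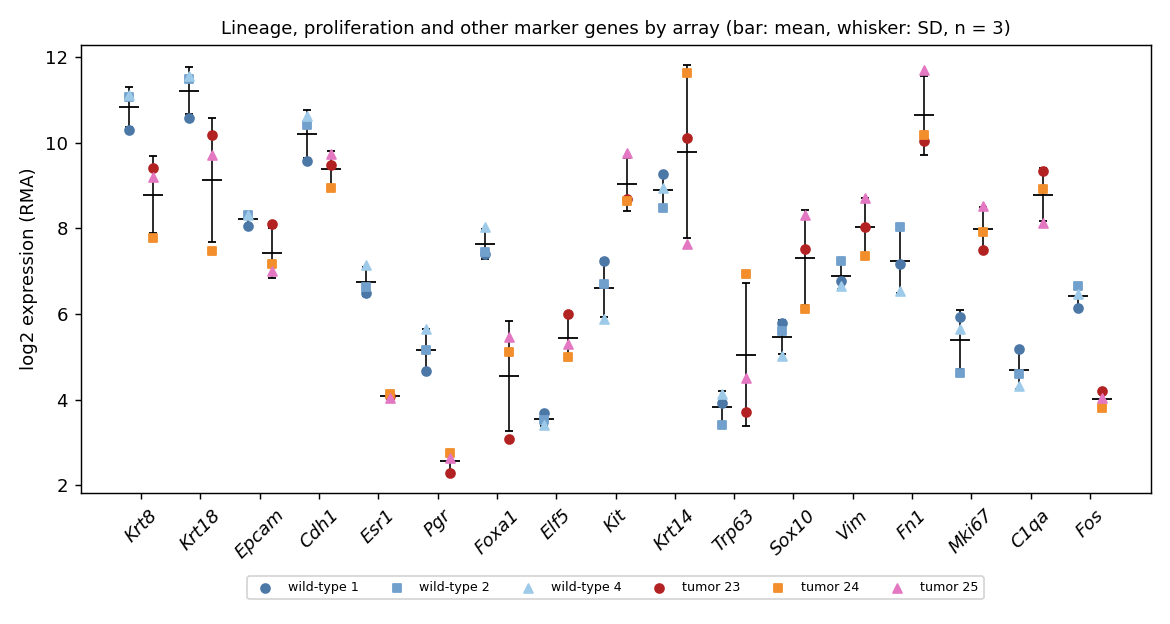
Log2 expression (RMA) of 17 marker genes on the y axis, with wild-type arrays to the left (blue) and tumors to the right of each position; bars are means and whiskers SD of 3 arrays. Esr1, Pgr and Fos lie lower in all 3 tumors and Elf5, Kit, Fn1, Mki67 and C1qa higher, while Trp63 lies apart in tumor 24.

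Mesenchymal genes were higher in tumors. Fn1, the matrix protein fibronectin, rose from 7.24 ± 0.75 to 10.6 ± 0.93 (SD, n = 3), 10.5-fold with an adjusted p of 0.033 in limma. The galectin Lgals1 rose by 2.29, the receptor kinase Axl by 1.70 and the matrix metalloprotease Mmp2 by 1.45. Of 18 measured, 4 rose and none fell (10 rose adjusted over the list alone); the list median was 1.22 and camera's adjusted p 3.03e-06, with adjusted p = 0.17 with an estimated correlation. Vim did not pass (1.15 ± 0.37, SE, adjusted p of 0.12 in limma), and its dimmer probe set was lower in tumors (-0.39). The list of fibroblast and matrix markers was higher too in tumors 23 and 24, with medians of 1.05 and 1.15 against the wild-type mean. In tumor 25 its median was -0.10, where that of the mesenchymal list was 1.13. The fibroblast and matrix members Bgn (11.84), Fbln2 (9.91) and Pdgfrb (6.60) still lay above every wild-type array there, and Col1a1 (4.98) did not. These medians therefore do not tell RNA of fibroblasts apart from a change in tumor cells. The proteoglycan Bgn (2.93, with a dimmer probe set at -0.22), Fbln2 (2.96) and the receptor Pdgfrb (2.56) rose, Gsn fell by 1.66, and 18 of 22 did not pass, among them the collagen gene Col1a1 (1.18 ± 0.94, SE). That list had a camera adjusted p of 0.013, of 0.13 without tumor 24, of 0.075 after quantile normalization again and of 0.10 after cyclic loess, and adjusted p = 0.51 with an estimated correlation. Adjusted over the list alone, 6 rose and 2 fell. In the list of neural crest and fetal mammary genes, Nkd2 and the forkhead gene Foxc1 (2.17) rose and the homeobox gene Msx2 fell by 1.90, to values under the background mark in all 3 tumors; of 16 measured, 3 rose and 3 fell adjusted over the list alone. Its median was -0.16, its mean 0.48 and camera's adjusted p 0.68. Sox10 measured 1.85 ± 0.55 (SE) higher, without passing (adjusted p of 0.11 in limma).

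All 24 measured mitotic genes and all 23 measured replication genes had higher means in tumors. Mki67, the proliferation marker, rose from 5.40 ± 0.69 to 7.98 ± 0.51 (SD, n = 3), with an adjusted p of 0.032 in limma. Cenpf (1.88) and Cenpe (1.73), both of the kinetochore, and the checkpoint kinase Bub1 (1.67) rose, and the other 20 mitotic genes did not pass over all genes, although 20 of 24 did adjusted over the list alone. The median was 1.88, and the list mean was 7.08 in tumor 25, 6.40 in tumor 23 and 5.29 in tumor 24, against 3.89 to 4.8 in wild-type arrays. Camera gave an adjusted p of 1.42e-11, and adjusted p = 0.48 with an estimated correlation. Of the replication genes, the helicase subunit Mcm7 (1.98) and the chromatin assembly gene Chaf1a (1.52) rose, and 5 did adjusted over the list alone. For this list camera gave an adjusted p of 1.89e-07, and adjusted p = 0.49 with an estimated correlation. Of 22 genes of homologous recombination and the Fanconi anemia pathway, only Brca2 rose (1.79 ± 0.22, SE, adjusted p of 0.018 in limma), with 5 adjusted over the list alone, and 21 had higher means; the median was 0.55. Camera's adjusted p for that list was 6.27e-06, and adjusted p = 0.40 with an estimated correlation. Its mean in wild-type cells was 3.72, at the level of the background mark, and Brca2 lay under that mark on all 3 wild-type arrays.

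Targets of p53 did not pass as a list, with a camera adjusted p of 0.63 and a median of -0.21, but passed downward under both filters on dim genes (0.0023 with a mean of at least 5 and 0.045 with a mean of at least the median). The genes kept by these filters had median differences of 0.32 and 0.27, so the list was set against genes mostly higher in tumors. Of 23 measured, the mitotic gene Ckap2 (1.97) and the death receptor Fas (1.17) rose and the polymerase Polk fell by 1.39, while 4 rose and 3 fell adjusted over the list alone. The cell cycle inhibitor Cdkn1a (-0.90 ± 0.55, SE) and the p53 ligase Mdm2 (-0.06 ± 0.27) did not pass, nor did the oncogenes Myc (-0.43 ± 0.29) and Met (-0.14 ± 0.30).

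Glycolytic and hypoxia-inducible genes were higher in tumors. The angiogenic factor Vegfa rose from 7.17 ± 0.39 to 9.60 ± 0.49 (SD, n = 3), 5.41-fold with an adjusted p of 0.019 in limma. The glycolytic enzymes Pfkp (2.30) and Pgam1 (1.62) and the collagen hydroxylase P4ha1 (2.10) rose, so that 4 of 17 rose and none fell, with 10 adjusted over the list alone. The median of the list against the wild-type mean was 1.49 in tumor 23, 1.52 in tumor 25 and 0.72 in tumor 24; over the 3 tumors it was 1.41 and camera's adjusted p was 1.90e-06, with adjusted p = 0.40 with an estimated correlation. The skeletal muscle list was also high in tumors 23 and 25, though not in step with it. Its mean was 8.75 in tumor 23, 5.94 in tumor 25 and 3.72 in tumor 24, against 3.53 to 3.71 in wild-type arrays. None of its 12 genes passed singly, over all genes or adjusted over the list alone; the sarcoplasmic calcium pump Atp2a1 measured 7.15 ± 3.58 in tumors and Mylpf, a myosin light chain, 5.78 ± 3.41 (SD, n = 3). Its camera adjusted p was 3.22e-04, and adjusted p = 0.65 with an estimated correlation. None of 19 oxidative phosphorylation genes passed, over all genes or adjusted over the list alone. Ndufs1 measured 1.98 and Ndufa9 1.68 higher, and camera's adjusted p was 0.076, past the threshold without tumor 24 and without wild-type replicate 2 (0.0017 and 0.038), and with array weights (0.018). In the lipid synthesis list, Thrsp rose and the triglyceride enzyme Dgat2 fell by 3.38, and 3 rose and 2 fell adjusted over the list alone. Its camera adjusted p was 0.040, and adjusted p = 0.72 with an estimated correlation; it was 0.23 without wild-type replicate 1, 0.062 without replicate 2, 0.13 without tumor 25, 0.17 after quantile normalization again and 0.23 after cyclic loess. Of the housekeeping list, Gapdh rose by 1.08 and 16 of 17 did not pass (5 rose adjusted over the list alone). Its camera adjusted p was 0.018, of 0.16 without tumor 25, 0.060 without wild-type replicate 1, 0.095 after quantile normalization again and 0.098 after cyclic loess, and adjusted p = 0.67 with an estimated correlation.

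Phagocyte genes were higher in all 3 tumors. C1qa rose from 4.70 ± 0.44 to 8.79 ± 0.61 (SD, n = 3), with an adjusted p of 0.011 in limma, and the cathepsin Ctss (3.09) and the colony-stimulating factor receptor Csf1r (2.67) rose as well. Of 19 macrophage and myeloid markers, 10 rose and none fell (17 rose adjusted over the list alone); the median was 1.66. The list had a camera adjusted p of 5.8e-13, and adjusted p = 0.40 with an estimated correlation. Ptprc, the pan-leukocyte antigen, measured 1.63 ± 0.60 (SE) higher without passing (adjusted p of 0.16 in limma). No member of the T and NK cell, B and plasma cell, neutrophil, pericyte, adipocyte or keratinocyte lists passed over all genes, and camera's adjusted p over these lists lay between 0.11 and 0.62. Adjusted over the list alone, 1 neutrophil gene rose and 1 fell, 1 pericyte gene rose, and none of the other 4 lists had a call. The largest differences there were Nkg7 (-0.92) and Gzma (-0.84), Jchain (1.58) and Ighm (1.03, with other probe sets of both signs), Csf3r (1.79) and Mmp9 (1.76), Des (2.08) and Mcam (1.53), Fabp4 (-2.87) and Car3 (2.27), and Krt6a (-1.85) and Calml3 (1.16). Gzma lay under the background mark on 2 wild-type and 3 tumor arrays, and Csf3r and Mmp9 on 3 wild-type arrays. Mean levels in wild-type cells and tumors were 3.76 and 3.45 for T and NK cell genes, and 3.48 and 3.42 for B and plasma cell genes. Neutrophil genes were at 3.46 and 3.76. All lay near the background mark, so the missing calls say little about these cells. Des was at 9.96 in tumor 23, where the muscle list was highest, and at 3.97 and 4.92 in tumors 24 and 25; without tumor 23, Des measured 0.24 and Car3 0.92 higher. The keratinocyte list passed camera downward without tumor 24 (0.024). Its median against the wild-type mean was 0.86 in tumor 24, and -0.49 and -0.52 in tumors 23 and 25. Among 19 endothelial genes only Vwf passed, falling by 1.01, also adjusted over the list alone. Pecam1 measured -0.41 ± 0.44 (SE), and camera's adjusted p was 0.84.

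**Figure D3:**
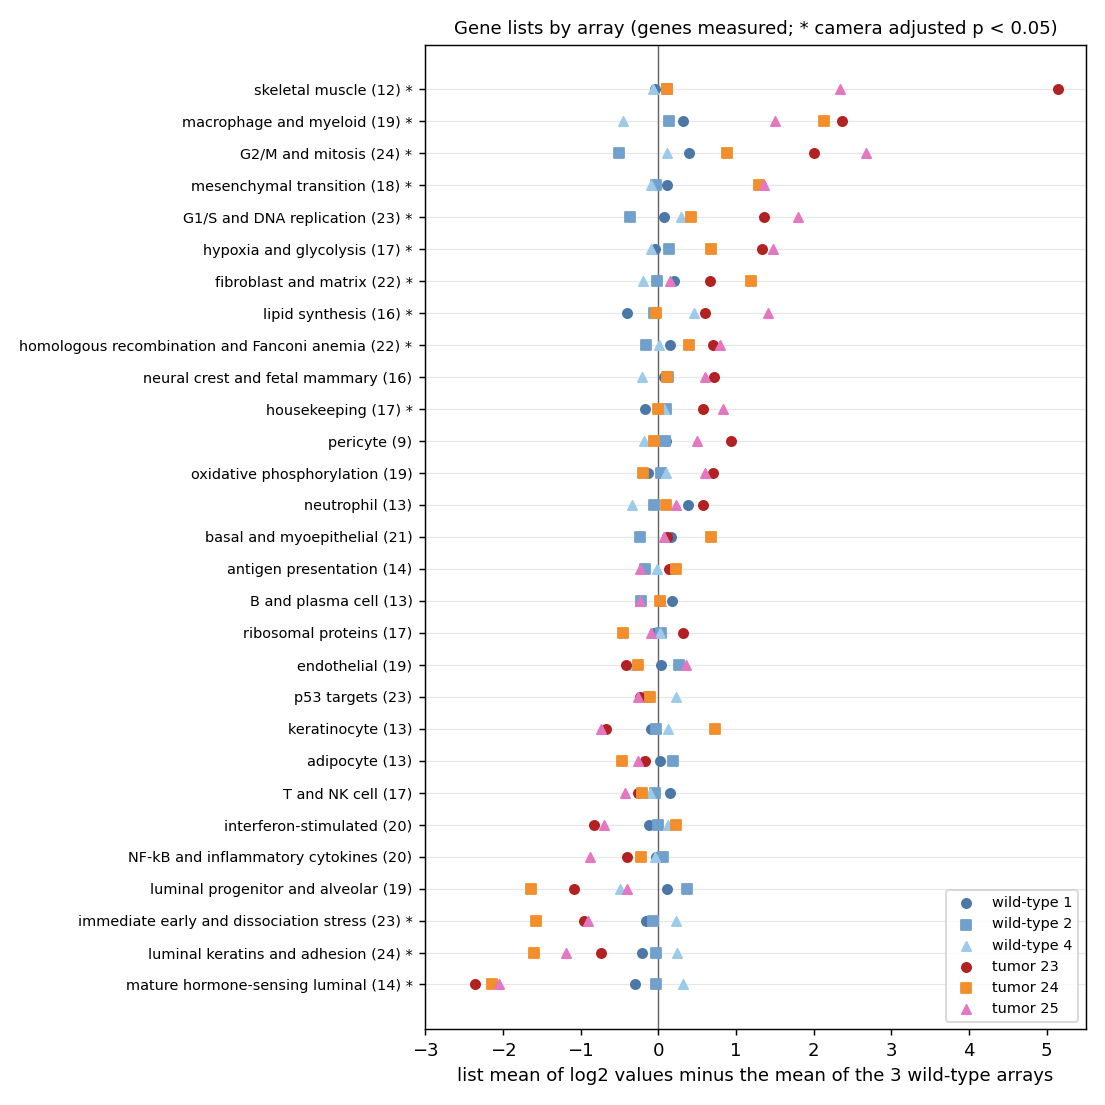
Each row is a gene list with its number of measured genes; the x axis gives the list mean of log2 values on each array minus the mean of the 3 wild-type arrays, and an asterisk marks a camera adjusted p under the threshold with the preset correlation. The skeletal muscle list lies far right in tumors 23 and 25 but not in tumor 24, and the mature hormone-sensing list lies left in all 3 tumors.

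Several immediate early and inflammatory genes were lower in tumors than in the sorted cells. The groups also differed in time since the virus, and its part was not tested. Fos fell from 6.42 ± 0.26 to 4.01 ± 0.20 (SD, n = 3) with an adjusted p of 0.0089 in limma, and Fosb, Klf6 (by 2.49) and the RNA-destabilizing Zfp36 (by 2.40) fell too. This list holds genes that tissue dissociation can induce, and only the wild-type cells are described as sorted. Of 23 measured, 6 fell and none rose (11 fell adjusted over the list alone), with a median of -0.96. As a list they had a camera adjusted p of 3.32e-05, and adjusted p = 0.48 with an estimated correlation. Of 20 measured NF-kB and cytokine genes, 4 fell: Il6 (by 4.07), Cxcl1 (by 1.83), the inhibitor Nfkbia (by 1.59) and Relb (by 1.36), and the same number did adjusted over the list alone; camera's adjusted p was 0.11, and 0.0071 and 0.0039, downward, after quantile normalization again and cyclic loess, and 0.024 without tumor 24. Of 20 interferon-stimulated genes, only Rsad2 passed, over all genes and adjusted over the list alone, and fell by 2.24. That list had a camera adjusted p of 0.32, of 0.036 and 0.019, downward, under the same scalings and of 0.0021 without tumor 24. None of 14 antigen presentation genes passed over all genes (1 rose adjusted over the list alone), with H2-Ab1 at 1.21 and H2-Aa at 1.09 and a camera adjusted p of 0.75. Its median was -0.23, its mean 0.05 and camera's direction upward, which turned after quantile normalization again and cyclic loess. None of 17 ribosomal protein genes passed over all genes and 1 fell adjusted over the list alone. Rpl3 measured -1.87 and Rplp0 1.35, both with probe sets of either sign, and camera's adjusted p was 0.99, downward, with the direction turned after cyclic loess. The ribosomal list median against the wild-type mean was -0.19 in tumor 24, 0.17 in tumor 23 and -0.11 in tumor 25.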

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

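In this part, the tests chosen only after the result was seen were those of epithelial share, scaling and luminal subtypes for the hormone-sensing genes, and those of muscle RNA, with its covariate, and of matched random lists for the hypoxia genes. The other scalings themselves, like the test of single probe sets and the counts over splits, were chosen before the results were seen.

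Of 17824 probe sets that name no gene or several, and so entered no comparison, 110 passed limma's test when all 41345 probe sets were tested singly, 73 higher and 37 lower in tumors. They drew attention as signal outside the genes compared. No group was large enough for a test of single outlying arrays.

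The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 867 genes and 818 genes of at least 2-fold, and the highest of the others gave 0 of either, so that 1 split of 10 was as large for each count. For gene lists passing camera with the preset correlation, the real split gave 13 and the highest other 15, and 4 of the 10 splits, the real one included, gave 13 or more.

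Of 14 genes of hormone-sensing luminal cells 7 fell in the tumors, with a list median of -1.77. A smaller share of epithelial cells in tumor tissue would lower keratin and adhesion genes by about as much. Of 23 such genes (1 shared with the mature list left out), 10 had a 95% confidence interval wholly above that median, among them Grhl2 (0.63) and Esrp1 (-0.04). At or below it were 6, among them Krt8 (-2.05) and Krt19 (-4.36). Members of the mature list itself, such as Cited4 (0.15), also had intervals wholly above its median, so the count cannot decide. The lists were not tested against each other. Against the wild-type mean, the keratin and adhesion median was -1.83 in tumor 24, near the mature list's -2.02. It was -0.72 in tumor 23 and -0.88 in tumor 25, against -1.96 and -2.11. Camera's adjusted p was at most 2.11e-09 under 3 other scalings, although the call is lost with an estimated correlation (adjusted p = 0.25). Camera sets a list against the other genes, so a shift common to all genes largely cancels. These values show that the fall relative to other genes was kept, and do not decide on scaling. Another mix of luminal subtypes among the sorted cells cannot be told apart from a change in the tumors, since the progenitor and alveolar list had a median of -0.90 with members moving both ways (camera's adjusted p of 0.11, and of at most 0.019, downward, under 3 other scalings) and no sorted subtype was analysed here. A loss of hormone-sensing identity in the tumors, or an origin in cells that lacked it, may also account for the fall and stays an untested hypothesis.

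Hypoxia-inducible and glycolytic genes were higher in tumors, and skeletal muscle genes, which come with glycolytic enzymes, were high in tumors 23 and 25. In tumor 24, with muscle genes at the wild-type level, the hypoxia list median was 0.72 above the wild-type mean, against a largest deviation of 0.29 of a wild-type array from the others, and 1.49 and 1.52 in tumors 23 and 25. Muscle list medians were 5.37 in tumor 23 and 2.30 in tumor 25, so the hypoxia list did not follow the amount of muscle RNA between them. With only 1 tumor at the wild-type muscle level, muscle RNA cannot be told apart from a change in tumor cells. The hypoxia list kept its call with the muscle covariate (camera's adjusted p of 1.26e-04). The wild-type arrays all lie near the muscle level of tumor 24, so that value rests largely on tumor 24 and is little further support. A brighter upper range of the tumor arrays is argued against by a permutation test on random lists of matched expression (two-sided p = 2.0e-04, the smallest that 10000 lists can give). Low oxygen or altered metabolism in tumor tissue may underlie the rise, as a hypothesis that these arrays do not test, and the list's call is lost with an estimated correlation (adjusted p = 0.40).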

How the results depend on the processing

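The muscle covariate, tumor 24 alone and the matched random lists were chosen after seeing the data; the other alternatives were planned. All 867 genes kept their direction in every alternative that tested them, except 2 under the mean of a gene's probe sets. Of the named genes that passed, none reversed. The groups did not overlap for any of the 867, so leaving out arrays, tumor 24 alone and array weights cannot reverse a direction. The filters on dim genes, the trended robust prior and single probe sets, read at each gene's brightest one, leave the differences themselves unchanged. In these alternatives the kept direction was therefore fixed in advance and is no sign of robustness. The call of the named genes that passed was lost in 233 of 420 leave-one-out values and in 196 of 750 others. Where fewer arrays enter, fewer degrees of freedom remain; for the other lost calls the cause was not tested. No paired analysis was possible because the groups share no replicate numbers. Genes under the 2 filters on dim genes, and lists with fewer than 3 genes left, gave no value there. Genes near background, as Brca1 in wild-type cells, have compressed differences.

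Leaving out each array, the number of genes ranged from 72 to 1200 and of those at least 2-fold from 72 to 1185, and the spread ratio from 0.76 to 1.52. Camera's adjusted p ranged from 0.0031 to 0.23 for lipid synthesis, 0.00053 to 0.16 for housekeeping, 2.7e-05 to 0.13 for fibroblast and matrix, 0.24 to 0.997 for ribosomal proteins, 0.20 to 0.98 for endothelial, 0.24 to 0.97 for neutrophil, 0.39 to 0.99 for antigen presentation, 0.024 to 0.92 for keratinocyte and 0.24 to 0.95 for basal genes. The last 6 changed direction without passing in it. Calls were gained by progenitor and alveolar (0.0076 to 0.24, lowest without tumor 25), and, lowest without tumor 24, by interferon-stimulated (0.0021 to 0.68), NF-kB (0.024 to 0.35), oxidative phosphorylation (0.0017 to 0.59) and keratinocyte genes. Differences ranged from -0.25 to 0.13 for Mdm2, -0.42 to 0.037 for Met and -0.031 to 1.97 for Krt14. Without changing sign, they moved by more than 1.5 times for Krt18 (-2.62 to -1.26), Krt6a (-3.52 to -0.74), Des (0.24 to 3.24), Car3 (0.92 to 3.82), Atp2a1 (2.43 to 5.98), Mylpf (1.80 to 5.21), Col1a1 (0.30 to 2.18), Trp63 (0.28 to 1.89), Calml3 (0.46 to 1.72), Ighm (0.11 to 2.18), Jchain (0.98 to 2.01), Mmp9 (0.91 to 2.25), Cdkn1a (-1.23 to -0.40), Myc (-0.61 to -0.14) and Pecam1 (-0.75 to -0.06), none of which had passed. Atp2a1, Mylpf, Car3, Csf3r, Mcam and Sox10 passed upward without tumor 24.

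Probe sets tested singly gave 376 calls, all at least 2-fold, housekeeping centring 1359, all at least 2-fold, with a spread ratio of 1.64, and array weights 1324. Named genes that had not passed but did in these and the following alternatives were Krt8 and Rpl3 under both filters on dim genes, all 3 scalings and the trended robust prior, Rpl3 also with array weights, Nkg7 under the 3 scalings, Fabp4 under both filters and housekeeping centring, Mcam under both filters and with array weights, Ndufs1 under both filters, Sox10 under the first, Csf3r under that prior, and Atp2a1, Cdh1 and Krt18 under housekeeping centring, all in their first direction. With a mean of at least 5, adjusted p was 0.69 for lipid synthesis, 0.58 for fibroblast and matrix and 0.59 for housekeeping; basal (0.37), antigen presentation (0.22) and pericyte (0.83) lists reversed. With a mean of at least the median these were 0.50, 0.23 and 0.35, and basal (0.49) and antigen presentation (0.33) reversed. After quantile normalization again they were 0.17, 0.075 and 0.095, and basal (0.81) and antigen presentation (0.53) reversed. After cyclic loess they were 0.23, 0.10 and 0.098, and basal (0.76), antigen presentation (0.56) and ribosomal (0.97) lists reversed. The ribosomal list also reversed under the mean of probe sets (0.75), the trended robust prior (0.88) and array weights (0.72), and the endothelial list under that prior (0.997).

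With the muscle covariate 31 genes passed, all at least 2-fold; adjusted p was 0.26 for lipid synthesis and 0.27 for housekeeping. Reversed were the muscle list itself (0.96, as its mean was the covariate) and the neural crest (0.93), p53 (0.99), interferon (0.42), oxidative phosphorylation (0.60), neutrophil (0.99), endothelial (0.93) and keratinocyte (0.25) lists, with Car3 (-0.62), Des (-0.99), Krt6a (0.32), Mdm2 (0.14) and Myc (0.068). Tumor 24 alone gave 0 genes in limma (3588 at an unadjusted p under 0.05), with the spread then that of wild-type arrays. Adjusted p was 0.54 for lipid synthesis, 0.61 for skeletal muscle and 0.92 for housekeeping; neural crest (0.72), p53 (0.99), interferon (0.083), oxidative phosphorylation (0.20) and keratinocyte (0.020) lists reversed, with Car3 (-0.83), Des (-0.23), Krt6a (1.51) and Mdm2 (0.30). Calls were gained there by basal (0.021) and keratinocyte genes upward and by ribosomal (0.041) and progenitor and alveolar genes (0.0052) downward.

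With an estimated correlation 0 lists passed, at adjusted p of 0.17 for mesenchymal, 0.25 for mature luminal, 0.40 for homologous recombination, hypoxia and macrophage, 0.48 for keratins, mitosis and immediate early, 0.49 for replication, 0.51 for fibroblast, 0.65 for muscle, 0.67 for housekeeping and 0.72 for lipid synthesis. Fry passed 8 lists and lost replication (0.11), mitosis (0.072), lipid synthesis (0.66), fibroblast (0.23), muscle (0.28) and housekeeping (0.28). Against matched random lists, fibroblast (0.074) and housekeeping (0.31) were lost, and the medians of neural crest (0.48) and antigen presentation (0.15) lay below the median of all genes, opposite to camera's direction. Calls were gained against matched random lists by progenitor and alveolar (0.00058), interferon (0.0011) and NF-kB genes (0.011), with fry by adipocyte genes (0.046) and with array weights by oxidative phosphorylation (0.018). Progenitor and alveolar, NF-kB and interferon genes also passed downward under quantile normalization again, cyclic loess and both filters on dim genes, progenitor and alveolar genes under housekeeping centring, and p53 targets under both filters (0.0023 and 0.045). Under the filters, camera set these lists against genes with a median difference of 0.32 or 0.27.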

Other observations

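All tests in this part but the correlation between dim and bright genes were chosen only after the result was seen; 5 gene lists were written after the largest changes were known and adjusted over these 5.

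Genes that hydroxylate and crosslink collagen, in a list that left out Plod2 and Loxl3, had higher means in tumors for all 12 measured. P4ha1 rose by 2.10 ± 0.32 log2 units (SE) and Pcolce, an enhancer of procollagen processing, by 2.12 ± 0.34, both passing limma's test; 6 rose adjusted over the list alone. The median was 1.18 and camera's adjusted p 8.55e-06, with adjusted p = 0.13 with an estimated correlation, 0.011 with fry and 0.0050 against matched random lists. P4ha1 is also in the hypoxia list. Complement and lysosomal genes of phagocytes had a median of 0.47: of 17 measured, Lgmn (1.33) and C1qc (1.66) rose, and 5 did adjusted over the list alone. Camera's adjusted p was 0.0062, and adjusted p = 0.14 with an estimated correlation; it was 0.011 with fry, and the call was lost against matched random lists (0.12).

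Some interferon-gamma-inducible genes were far lower in tumors than in wild-type cells, which were taken sooner after the virus. A part of the virus in this difference cannot be told apart from a change in the tumors. Cxcl9, a T cell chemokine, fell from 9.21 ± 0.13 to 5.99 ± 0.35 (SD, n = 3), Iigp1 fell by 3.53 and Ido1 by 3.39, with adjusted p of 0.0063, 0.020 and 0.024 in limma; these 3 were chosen after their values were seen. In a list of 16 other such genes only Gbp10 passed, over all genes and adjusted over the list alone, and fell by 1.93. Its median was -0.34; it did not pass camera (adjusted p of 0.17, and adjusted p = 0.27 with an estimated correlation) and passed downward with fry (0.048) and against matched random lists (0.022). Of 17 acute phase and secretory defence genes only Ceacam1 passed and fell by 2.91, and 2 fell adjusted over the list alone. The list median was -0.51, with -1.55 in tumor 24 and -0.26 and -0.28 in tumors 23 and 25. Camera's adjusted p was 0.23, and adjusted p = 0.61 with an estimated correlation. Adjusted p was 0.14 with fry and 0.0050, downward, against matched random lists. In a list of 20 receptors and ligands of the FGF and ERBB families, which left out Fgfr2, none passed, over all genes or adjusted over the list alone (median -0.19, camera's adjusted p of 0.51, 0.22 with fry and 0.29 against matched random lists).

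Chromosome medians differed between the tumors. Over 7685 genes with a mean of at least 5, the SD of chromosome medians, each array against the mean of the other arrays of its group, was 0.149, 0.116 and 0.150 in tumors 23, 24 and 25 and 0.038, 0.066 and 0.027 in wild-type replicates 1, 2 and 4, the smallest tumor value being 1.76 times the largest wild-type value. Chance placement of genes is argued against by permuted chromosome labels (p = 0.001 in each tumor, the smallest that 1000 permutations can give), although wild-type replicate 2 also gave 0.011. Dim and bright genes moved together, with r across the chromosomes of at least 0.69 in tumors and at most 0.42 in wild-type arrays, where the medians varied little. Other tissues in the tumor pieces can hold dim and bright genes alike, so this r does not decide on them. Copy number changes that differ between tumors may account for the chromosome shifts, with chromosome 13 at 0.31 in tumor 23 and -0.36 in tumor 25 (chromosomes as in assembly GRCm38.p6), but the deviations of 3 tumors from each other are not independent and no DNA was analysed here.

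Xist, the RNA that coats the inactive X chromosome, measured 9.52 in tumor 23, 11.07 in tumor 24 and 4.24 in tumor 25, against 9.48, 9.20 and 8.82 in wild-type replicates 1, 2 and 4.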
